A study of Mus musculus with 9 samples.

How the data were processed

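The study grew mouse pulmonary microvascular endothelial cells, the cells that line the small vessels of the lung, bought from a commercial supplier, for 48 h. The 3 conditions were sampled as 3 libraries each. RA was room air with 21% oxygen, HO was hyperoxia with 85% oxygen, and HO-rWNT5A was the same hyperoxia with 100 ng/ml recombinant WNT5A protein, a secreted WNT ligand. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

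Per the labels' protocols, total RNA libraries were made with a kit for human, mouse or rat RNA and read as 150-base pairs, adapters were trimmed with Skewer 0.2.2, and reads were aligned with STAR 2.5.3a to an Ensembl reference. Transcripts were then assembled with StringTie 1.3.1 and merged, and the merged set was set against the Ensembl annotation with gffcompare 0.9.9c. The submitters' processing notes also name FastQC 0.11.2 and DESeq2, and list the builds hg38 and mm10 without saying which applied. The identifiers in the table are those of mouse. The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, for 143043 transcripts in 9 libraries.

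Of the transcripts, 142351 had an Ensembl mouse identifier, and 141441 of those (99.36%) were found in GENCODE M21 (GRCm38, the assembly also called mm10), from which names and coordinates were taken. A further 692 were assembled transcripts from 530 loci without an Ensembl identifier, kept as loci of their own. FPKM was summed over the transcripts of a gene. FPKM hides read depth, so depth was estimated from the most common product of FPKM and transcript length among genes with 1 transcript, taken as the worth of 1 untrimmed fragment. This gave 21300000 to 26500000 fragments per library, or 42.6 to 53.1 fragments behind 1 FPKM for a transcript of 2000 bases. That product was held by 28 to 77 of the 6537 to 6962 transcripts looked at in a library. Between 5.3% and 7.4% of values were whole multiples of that worth within 0.02, little more than evenly spread values would give. This was too few to recover counts, so no count test was run and the depths are rough. Small structural RNA took 20.06% to 28.06% of a library's FPKM.

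Each library was scaled by the median ratio of its genes to their geometric mean. Genes with a mean of at least 1 FPKM over the 9 libraries were tested on log2(scaled FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model over all 9 libraries, contrasts, empirical Bayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Transcripts were tested in the same way with the library factors of the genes. Lists of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists of a comparison, and again with a correlation estimated from the data. Values are given as mean scaled FPKM ± SD with n = 3 per group. An exact permutation test of 3 libraries against 3 cannot go below p = 0.1. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

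The comparisons, the tests, the lists and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among named genes past the threshold whose groups did not overlap (predicted genes and pseudogenes left out), up to 4 members of each described list by smallest p, and 14 genes whatever their value. Genes outside this rule are said to be chosen after their values were seen. Some results that the rule covers are not reported here. Genes that passed in opposite directions in HO vs RA and HO-rWNT5A vs HO were also to be named. Alternatives fixed at the same time were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, FPKM as deposited, scaling to equal totals, quantile normalization, no variance trend, a robust variance, the 2 compared groups alone, the replicate number as a block, each library left out, and reference transcripts alone. For lists, the robust alternative used cameraPR on the moderated statistics, since camera has no such option. Alternatives added after the data were seen were protein-coding genes alone, scaling to the protein-coding total with structural RNA left out, removal of a trend with GC content and length, and leaving out HO replicates 2 and 3 together.

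The tests were checked on simulated data for the 13831 genes, drawn independently with the real means and 200 genes changed. The changes were made on the log2(FPKM + 1) scale. Each gene had its pooled spread in all groups alike. For HO vs RA, 84 of 100 genes changed 1.5-fold and 100 of 100 changed 2-fold were called, with 16 unchanged genes called. For HO-rWNT5A vs HO the numbers were 84 and 100 with 13 unchanged, and for HO-rWNT5A vs RA 88 and 100 with 9 unchanged. The real HO libraries varied more (median SD of a gene 0.123, against 0.074 in RA and 0.083 in HO-rWNT5A). Having 200 changed genes also eases the adjusted threshold. The shares called may thus be too high for a comparison with few changed genes. With the p53 target list shifted by a fixed small fold and nothing else, camera called it in each comparison and called 2, 0 and 2 of the 32 other lists, in the same order of comparisons. A simulated trend with GC content gave 3313 calls in HO vs RA before its removal and 0 after.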

Results

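RNA was measured in 9 libraries from cells labelled mouse pulmonary microvascular endothelial cells. Of these, 3 were kept in room air (RA), 3 in 85% oxygen (HO) and 3 in 85% oxygen with recombinant WNT5A (HO-rWNT5A). The roughly estimated depth was 26500000, 22700000 and 25400000 fragments in RA replicates 1, 2 and 3. It was 23000000, 21300000 and 21500000 in HO and 22600000, 21800000 and 23900000 in HO-rWNT5A. No pair of libraries held identical values. Libraries of a group correlated across genes with r from 0.9858 to 0.9932, and libraries of different groups with r from 0.9827 to 0.9909. Genes are not independent replicates here. The median SD of a gene on the log2 scale was 0.074 in RA, 0.123 in HO and 0.083 in HO-rWNT5A. On the principal components, HO replicate 2 lay farthest out on the second, HO-rWNT5A replicate 3 on the third and HO replicate 3 on the fourth. HO replicate 3 had 20.06% of its FPKM in small structural RNA, against 27.36% and 26.51% in HO replicates 1 and 2. Its share of retained-intron transcripts was 7.09%, against 5.49% and 5.26%.

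Most genes that mark endothelium were near 0. Of 27 pan-endothelial genes, 19 had a mean under 1 FPKM over the 9 libraries and 2 reached 5 FPKM. Pecam1, an endothelial adhesion molecule, had 0.093 ± 0.035 FPKM (SD, n = 9). Cdh5, the endothelial cadherin, had 0.0543 ± 0.018. Vwf, a clotting factor carrier stored in endothelial cells, had 0.0442 ± 0.058. The 2 above 5 FPKM were Flt1, a VEGF receptor, with 37.9 ± 4.6, and Emcn with 10.1 ± 1.1. Some genes of other cell types were abundant. Those named here beyond Pecam1, Cdh5 and Vwf were chosen after their values were seen. Acta2, smooth muscle actin, had 1580 ± 140 FPKM, and Des, the muscle intermediate filament desmin, had 366 ± 54. Col1a1, a fibrillar collagen, had 183 ± 23. The epithelial keratins Krt18 and Krt8 had 54.8 ± 5.6 and 31.2 ± 3.7. A mean of at least 5 FPKM was reached by 6 of 10 pericyte and smooth muscle markers, 3 of 10 fibroblast markers and 3 of 11 epithelial markers. The same held for 2 of 7 lymphatic endothelial, 1 of 6 mesothelial and 0 of 10 leukocyte and macrophage markers.

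**Figure D1:**
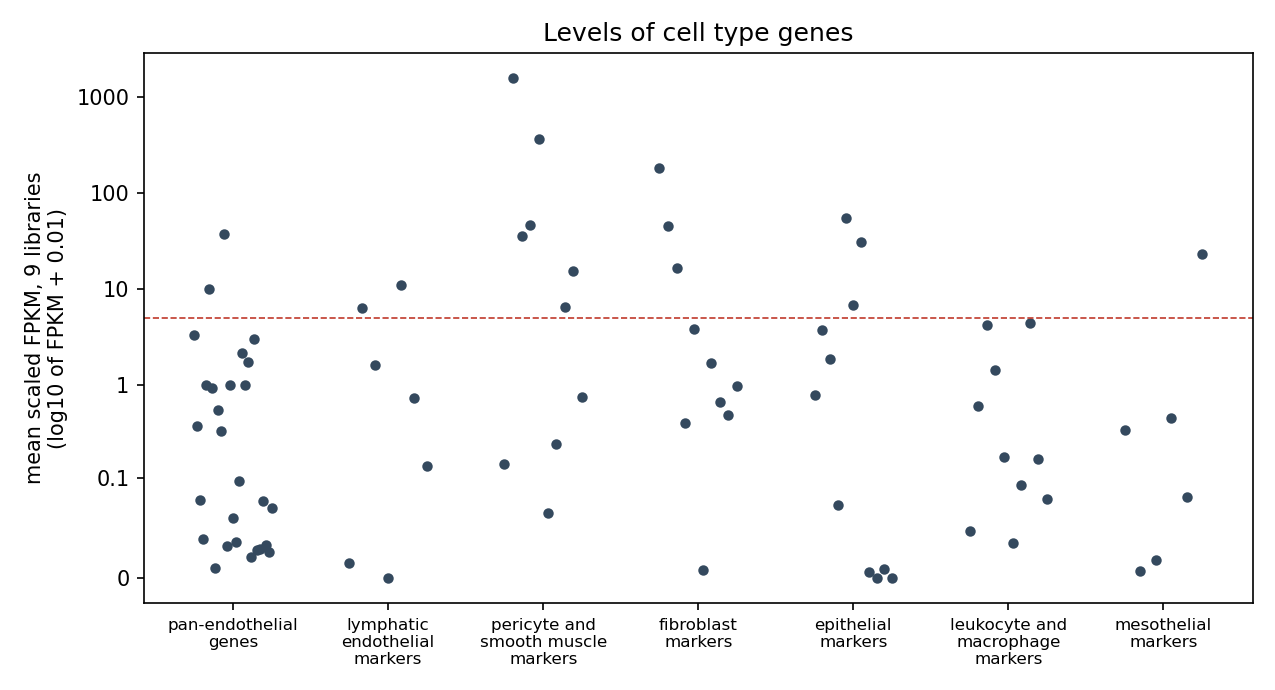
Mean scaled FPKM over the 9 libraries (vertical axis, logarithmic after adding 0.01) of each gene in 7 cell type lists, 1 point per gene, with a dashed line at 5 FPKM. Of the 27 pan-endothelial genes 2 lie above the line, while Acta2 among the pericyte and smooth muscle markers reaches 1580 FPKM.

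The first comparison, HO against RA, asked what hyperoxia changed. Targets of p53, the transcription factor activated by DNA damage, rose, and genes of mitosis fell. Cdkn1a, the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090976 to 29100727), had 206 ± 5.27 FPKM in RA and 289 ± 31.3 in HO, a log2 fold change of 0.48 ± 0.079 (SE, limma adjusted p = 0.0193). Plk1, a kinase that drives mitotic entry (chromosome 7, 122159439 to 122169873), had 3.93 ± 0.285 in RA and 1.88 ± 0.0863 in HO (log2 fold change -0.77 ± 0.10, adjusted p = 0.0111). Prc1, which organises the spindle midzone (chromosome 7, 80294450 to 80316259), fell from 9.13 ± 0.178 to 5.23 ± 0.26 (log2 fold change -0.70 ± 0.073, adjusted p = 0.009). Egr1, an early growth response transcription factor (chromosome 18, 34859823 to 34864984), rose from 21.4 ± 1.29 to 34.9 ± 1.25 (log2 fold change 0.68 ± 0.061, adjusted p = 0.00348).

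Of 24 p53 targets tested, 10 rose and 0 fell, with a median log2 fold change of 0.32, and 20 rose when adjusted over the list alone. The list had a camera adjusted p = 8.69e-16, and adjusted p = 0.0312 with an estimated correlation. The p53 targets that rose included Trp53inp1 (log2 fold change 0.56 ± 0.071), Btg2, an antiproliferative gene (0.48 ± 0.06), Eda2r (0.44 ± 0.063) and Ddit4l (0.36 ± 0.054). Of 25 mitosis genes tested, 14 fell and 0 rose, with a median of -0.44, and 22 fell when adjusted over the list alone. Camera gave adjusted p = 1.13e-20, and adjusted p = 0.0312 with an estimated correlation. The mitosis genes that fell included the B-type cyclins Ccnb1 (-0.67 ± 0.093) and Ccnb2 (-0.56 ± 0.078), and the proliferation marker Mki67 (-0.51 ± 0.095, adjusted p = 0.0315), which no longer passed in 10 of 21 alternatives. Of 17 immediate early genes 4 rose, or 10 when adjusted over the list alone. Besides Egr1 these were Egr3 (0.62 ± 0.079), Atf3 (0.86 ± 0.146) and Fosl1 (0.59 ± 0.101). The list had camera adjusted p = 1.51e-08 and adjusted p = 0.0395 with an estimated correlation.

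Other lists passed with the preset correlation but not with the estimated one. Of 19 genes of the unfolded protein and integrated stress response, 5 fell and 1 rose, or 10 and 3 when adjusted over the list alone (adjusted p = 0.000167, and adjusted p = 0.235 with an estimated correlation). Hspa5, a chaperone of the endoplasmic reticulum (chromosome 2, 34771970 to 34777547), had 102 ± 2.12 FPKM in RA and 74.5 ± 4.19 in HO (log2 fold change -0.45 ± 0.056). The chaperone Hsp90b1 (-0.41 ± 0.065) and Trib3 (-0.70 ± 0.103) fell too, while Atf3 rose. Of 19 cholesterol synthesis genes 5 fell, or 7 when adjusted over the list alone. Among them were Insig1 (-0.48 ± 0.077) and Hmgcs1 (-0.46 ± 0.085). The list had adjusted p = 4.99e-06 and adjusted p = 0.336 with an estimated correlation. Of 28 endothelial inflammation genes the filter left 11. Of these 2 rose, Lif (0.55 ± 0.073) and Nfkbia (0.43 ± 0.092), or 7 when adjusted over the list alone. Nfkbia no longer passed in 12 of 22 alternatives. Icam1, a leukocyte adhesion molecule in this list, had 4.27 ± 0.455 FPKM in RA and 6.81 ± 1.2 in HO (limma adjusted p = 0.052). The list had adjusted p = 1.21e-05, and adjusted p = 0.235 with an estimated correlation. Of 27 DNA replication genes 1 fell, Mcm4 (-0.39 ± 0.059), or 8 when adjusted over the list alone (adjusted p = 3.27e-05, and adjusted p = 0.102 with an estimated correlation). The 22 oxidative phosphorylation genes (median 0.09, adjusted p = 0.00738) and the 20 NRF2 antioxidant targets (median 0.10, adjusted p = 0.0478) had 0 members past the threshold. Adjusted over the list alone, 0 and 1 passed. Camera gave adjusted p = 0.66 and adjusted p = 0.655 with an estimated correlation. Without HO replicates 1 and 2 in turn, the former had adjusted p = 0.135 and 0.27, and the latter 0.0871 and 0.473. The NRF2 list no longer passed in 16 of 23 alternatives. Hmox1, a stress-induced heme oxygenase, had 26.6 ± 1.19 in RA and 28.9 ± 3.51 in HO (limma adjusted p = 0.613). The mesothelial list came down to 1 tested gene, Wt1, which fell (-0.41 ± 0.077; list adjusted p = 0.0478, and adjusted p = 0.235 with an estimated correlation). This list no longer passed in 11 of 23 alternatives, among them those without RA replicate 1, HO replicate 2 or HO replicate 3 (0.0556, 0.0577 and 0.115).

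The remaining 23 lists did not pass in HO vs RA. In the senescence list (adjusted p = 0.0648), which newly passed in 10 of 23 alternatives, Cdkn1a and Gdf15 rose and Lmnb1, a nuclear lamin, fell (-0.47 ± 0.083). Of the heat shock genes Hspa1b (0.57 ± 0.117) and Dnajb1 (0.29 ± 0.057) rose, but no longer passed in 10 of 21 and 13 of 22 alternatives. Apaf1 of the apoptosis machinery (0.38 ± 0.084) and Notch3 of the pericyte and smooth muscle markers (0.65 ± 0.128) rose as well, but no longer passed in 17 and 10 of 22 alternatives. With 0 members past the threshold were the pan-endothelial (list adjusted p = 0.362), lung capillary endothelial (0.232), junction and barrier (0.887) and Notch and angiogenesis genes (0.126). The same was so for WNT ligands and receptors (0.0648, newly passing in 4 of 23 alternatives), beta-catenin targets (0.984) and non-canonical WNT effectors (0.95). Other such lists were the other antioxidant enzymes, and the interferon-stimulated, mesenchymal transition and matrix, basement membrane, hypoxia-inducible, mitochondrially encoded, iron and ferroptosis and ribosomal protein genes. The fibroblast, leukocyte and macrophage, epithelial and lymphatic endothelial markers had 0 as well. The filter left 9 of 27 pan-endothelial, 6 of 17 lung capillary endothelial and 7 of 17 beta-catenin target genes, so the results of these lists cover few members. Ribosomal protein genes newly passed as lower in 9 of 23 alternatives. Median, mean and test differed in sign for the heat shock, junction and barrier, mitochondrially encoded and non-canonical WNT lists.

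Over all 13831 genes tested, 273 passed the threshold in HO vs RA, 164 higher and 109 lower. Of these, 7 changed at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes such as Plk1. Besides genes named above, the largest rises under the naming rule were in mt-Te, a mitochondrial transfer RNA (log2 fold change 1.07 ± 0.176), and Gla, the lysosomal alpha-galactosidase (1.05 ± 0.143). Next came S100a7a (0.98 ± 0.183), Nptx1 (0.97 ± 0.155), Tomm6 (0.94 ± 0.189), Zfp385a (0.82 ± 0.122), Prrg4 (0.82 ± 0.12) and Rgcc (0.79 ± 0.152). The largest falls were in the linker histone Hist1h1b (-0.93 ± 0.122), Pimreg (-0.88 ± 0.141), the mitochondrial folate enzyme Aldh1l2 (-0.85 ± 0.133), the microRNA gene Mir6993 (-0.83 ± 0.168) and Lsp1 (-0.82 ± 0.125). Next were the microRNA gene Mir3070a (-0.78 ± 0.145) and Mthfd2, another mitochondrial folate enzyme (-0.69 ± 0.088). Mir6993 lies inside Fads1 and Tomm6 overlaps other genes, so their values are uncertain. They no longer passed in 8 of 20 and 9 of 22 alternatives, mt-Te in 6 of 21 and Mir3070a in 9 of 20. The count was 24, 2 and 14 without RA replicates 1, 2 and 3, 109 without HO replicate 2 and 697 without HO replicate 3. The p53, mitosis and immediate early lists passed each time with the preset correlation. The split was 103 higher and 179 lower on FPKM as deposited, 21 and 23 with libraries scaled to equal totals, and 92 and 95 with scaling to the protein-coding total.

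Of 26158 transcripts tested, 4 passed in HO vs RA. The single transcript of Egr1 rose. A Cpsf1 transcript with 4.03, 3.78 and 3.19 FPKM in the RA libraries was listed at 0 in the other 6, and an H13 transcript fell (log2 fold change -1.17). The sums over all transcripts of Cpsf1 (limma adjusted p = 0.791) and H13 (limma adjusted p = 0.669) did not pass. The fourth had no match in the annotation. These transcripts were chosen after their values were seen.

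**Figure D2:**
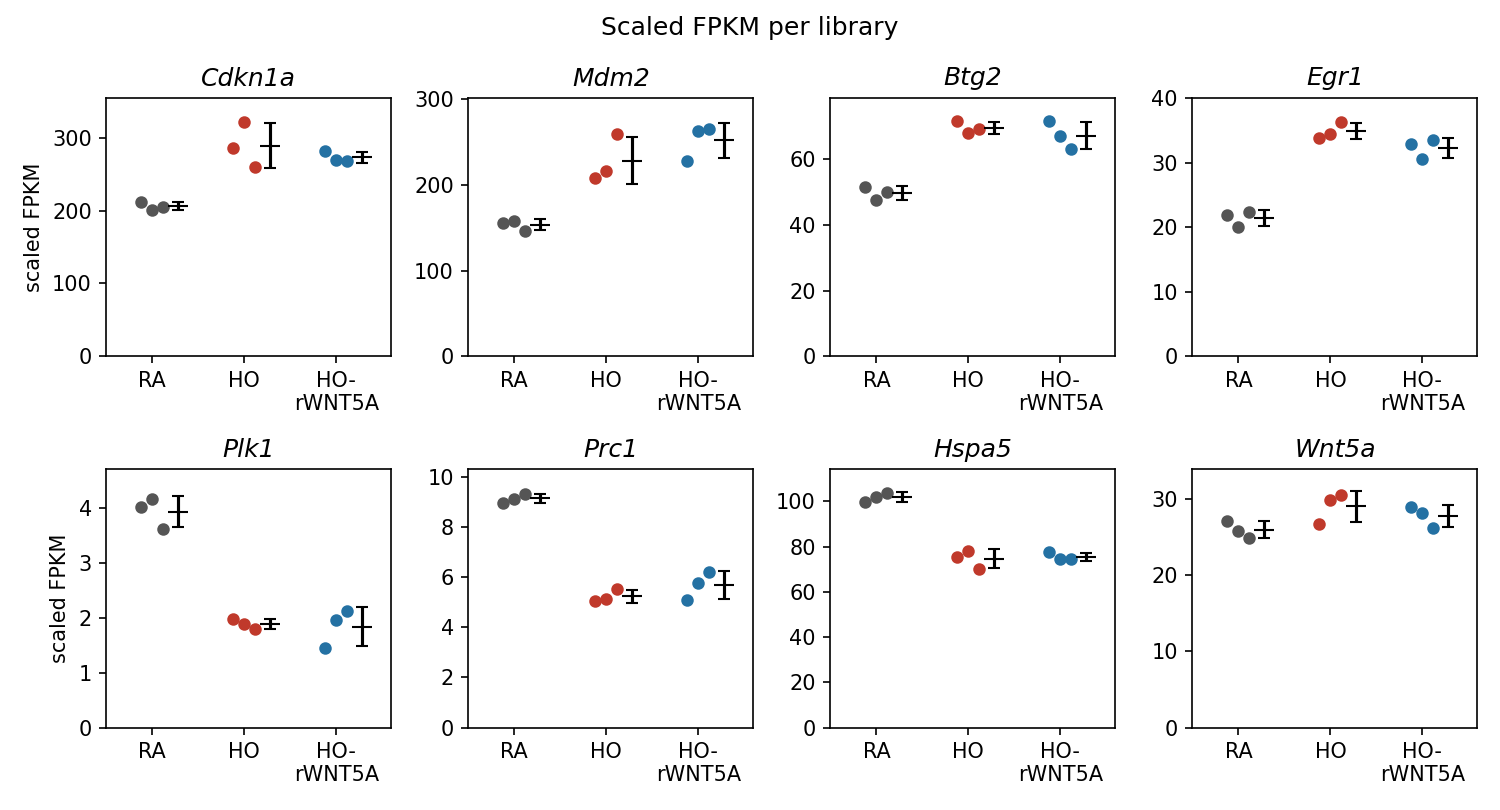
Scaled FPKM (vertical axes, from 0) of 8 genes in the 3 libraries of each group, 1 point per library, with the mean and SD (n = 3) beside the points. Cdkn1a, Mdm2, Btg2 and Egr1 lie higher, and Plk1, Prc1 and Hspa5 lower, in the 6 hyperoxic libraries than in RA, while Wnt5a had 26.0 ± 1.13, 29.1 ± 2.04 and 27.8 ± 1.44 FPKM in RA, HO and HO-rWNT5A.

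The second comparison, HO-rWNT5A against HO, asked what recombinant WNT5A changed under hyperoxia. Of 13831 genes, 1 passed the limma threshold, against 1280 at an unadjusted p under 0.05. That gene was a copy of the small nucleolar RNA gene Rnu3b1 (ENSMUSG00000098943.1, chromosome 11, 87443237 to 87443452), with 11.8 ± 1.84 FPKM in HO and 0.935 ± 0.751 in HO-rWNT5A. The annotation holds another Rnu3b1 entry (ENSMUSG00000105025.1) at 87443237 to 87443451, the same place, which had 1.86 ± 1.3 in HO and 15.8 ± 2.66 in HO-rWNT5A. The change is uncertain, since fragments of the same bases can be given to either entry. The sum over all Rnu3 copies was 66.8 ± 13.2 in HO and 84.8 ± 10.9 in HO-rWNT5A. Wnt5a itself (chromosome 14, 28504750 to 28527448) had 26.0 ± 1.13 FPKM in RA, 29.1 ± 2.04 in HO and 27.8 ± 1.44 in HO-rWNT5A. In limma its adjusted p was 0.25 for HO vs RA, 0.811 for HO-rWNT5A vs HO and 0.462 for HO-rWNT5A vs RA. Among WNT5A receptors, Ryk had 37.6 ± 2.35 in HO and 36.6 ± 0.919 in HO-rWNT5A (limma adjusted p = 0.871), Fzd4 3.05 ± 0.167 and 2.80 ± 0.154 (0.722) and Ror1 1.31 ± 0.0903 and 1.26 ± 0.143 (0.941). Ror2 (0.879 ± 0.0864 and 0.624 ± 0.083), the beta-catenin target Axin2 (0.959 ± 0.0929 and 0.908 ± 0.0911) and the antioxidant enzyme Nqo1 (1.03 ± 0.278 and 0.929 ± 0.217) lay below the filter and were not tested.

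Cdkn1a had a log2 difference of -0.08 ± 0.079, Mki67 0.11 ± 0.095, Hmox1 -0.05 ± 0.102 and Icam1 -0.06 ± 0.126. Their limma adjusted p were 0.798, 0.763, 0.925 and 0.907, past no threshold. Lists of p53 targets (median -0.05, adjusted p = 0.644), mitosis genes (-0.07, 0.381), beta-catenin targets (-0.11, 0.461) and non-canonical WNT effectors (-0.01, 0.995) did not pass. The filter left 7 of 17 beta-catenin targets and 23 of 27 non-canonical WNT effectors, so most beta-catenin targets were too low to test. With the preset correlation 4 lists passed. Hypoxia-inducible (median -0.12, adjusted p = 0.00205), oxidative phosphorylation (-0.08, 0.00443) and DNA replication genes (-0.07, 0.018) were lower, and cholesterol synthesis genes (0.09, 0.0082) higher. Each of the 4 had adjusted p = 0.788 with an estimated correlation. Leaving out 1 library ended 3 of these calls. Oxidative phosphorylation genes had 0.159 and 0.378 without HO replicates 1 and 2, and DNA replication genes 0.203 without HO replicate 2. Cholesterol synthesis genes had 0.503 without HO replicate 3 and 0.0666 without HO-rWNT5A replicate 1. Hypoxia-inducible genes had 0.36 without both HO replicates 2 and 3. They had 0 members past the threshold, also when adjusted over the list alone. The glycolytic enzyme genes Ldha (223 ± 35.3 and 176 ± 9.02 FPKM) and Pfkl (16.8 ± 2.34 and 13.2 ± 0.802) had limma adjusted p of 0.497 and 0.492. Median, mean and test differed in sign for the lung capillary endothelial, non-canonical WNT and immediate early lists.

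Of the 3 transcripts past the threshold, 1 was that of Rnu3b1 and 2 belonged to Sptan1, an alpha spectrin gene. The latter were chosen after their values were seen. One Sptan1 transcript was listed at 0 in the 6 other libraries and had 22.6, 48.7 and 20.4 FPKM in HO-rWNT5A. The sum over Sptan1 transcripts had a log2 difference of 0.14 (limma adjusted p = 0.497). Fragments of bases that transcripts of a gene share can be given to any of them, so these changes are uncertain. The count of genes was 32 without HO replicate 3, 24 of them lower, and 3 without HO replicate 2. It was 2, 5 and 5 without HO-rWNT5A replicates 1, 2 and 3.

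**Figure D3:**
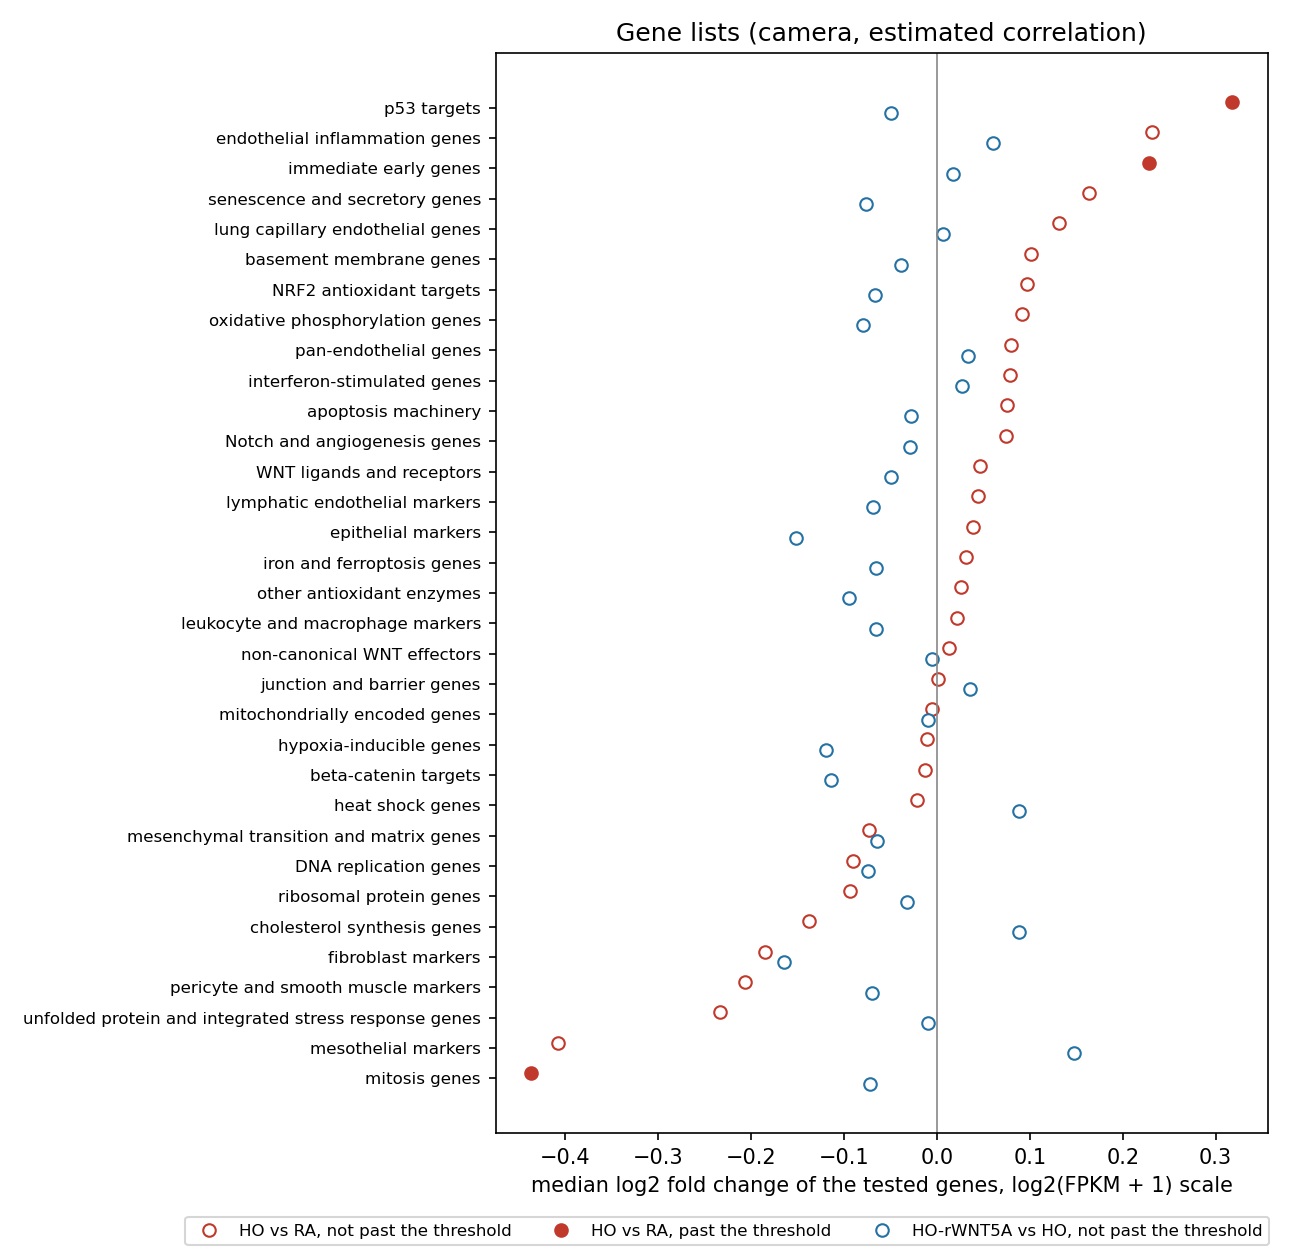
Median log2 fold change (horizontal axis, log2(FPKM + 1) scale) of the tested genes of each of 33 lists in HO vs RA (red) and HO-rWNT5A vs HO (blue), filled where the list passed in camera with an estimated correlation. Mitosis genes, at -0.44, and p53 targets, at 0.32, lie at the ends of HO vs RA, and 0 lists are filled in HO-rWNT5A vs HO.

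It was also asked whether recombinant WNT5A moved the genes of hyperoxia further or back. The number of genes past the threshold in both HO vs RA and HO-rWNT5A vs HO was 0 in opposite directions and 0 in the same direction in limma, where independent lists would share 0.02. At an unadjusted p under 0.05 in both, 279 genes went in opposite directions and 66 in the same direction. Both comparisons contain the HO libraries, which alone gave a covariance of fold changes of -0.0067 in 100 simulations of unchanged groups with the pooled spread (range -0.0081 to -0.0049). The observed covariance was -0.0105. The spread among the HO libraries themselves, a value looked at after this result, would give -0.011, so the covariance does not show that genes were moved back. The correlation of fold changes was -0.3406, against -0.4988 simulated (range -0.5507 to -0.3505). Signs were opposite for 60.8% of genes, against 66.8% simulated (range 65.9% to 67.6%). The simulation held no effect of hyperoxia. Genes that differ between HO and RA alone weaken the correlation and make the signs more even. Neither value therefore shows that genes were moved further. HO vs RA and HO-rWNT5A vs RA share the RA libraries, which by itself favours the same sign in both. Of the 273 genes past the threshold in HO vs RA, 273 had the same sign in HO-rWNT5A vs RA. Their median move from HO to HO-rWNT5A was -0.026 along the direction of HO vs RA. Over the 601 genes past the threshold in HO-rWNT5A vs RA it was 0.112 along the direction of that comparison. Each of these 2 sets was chosen by a change in one of the groups, which by chance alone favours a move back in the first and further in the second. The number of genes past the threshold in opposite directions was 12 without HO replicate 3, 1 without HO replicate 2 and 1 without HO-rWNT5A replicate 2.

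The third comparison set HO-rWNT5A against RA. Mitosis genes fell and p53 targets rose here too. Of 25 mitosis genes 15 fell, with a median of -0.47, or 23 when adjusted over the list alone. Camera gave adjusted p = 1.08e-20, and adjusted p = 0.0382 with an estimated correlation. Among them were Ccnb1 (-0.78 ± 0.093), Ccnb2 (-0.67 ± 0.078) and Ccna2 (-0.58 ± 0.072). Of 24 p53 targets 13 rose, with a median of 0.32, or 18 when adjusted over the list alone (camera adjusted p = 2e-12, and adjusted p = 0.0382 with an estimated correlation). Mdm2, the ubiquitin ligase of p53 (chromosome 10, 117688875 to 117710758), had 153 ± 6.54 FPKM in RA and 252 ± 20.8 in HO-rWNT5A. Gdf15 rose too (0.62 ± 0.086). Of 27 DNA replication genes 6 fell, or 14 lower and 1 higher when adjusted over the list alone. Those that fell included Mcm4 (-0.44 ± 0.059), Ccne2 (-0.49 ± 0.076) and Uhrf1 (-0.42 ± 0.071). The list had adjusted p = 9.6e-09 and adjusted p = 0.0382 with an estimated correlation. Of 17 immediate early genes 8 rose, or 11 when adjusted over the list alone, including Egr1 (0.57 ± 0.061), Fosl1 (0.64 ± 0.101) and the phosphatase Dusp1 (0.38 ± 0.057). The list had adjusted p = 8.08e-08 and adjusted p = 0.0386 with an estimated correlation.

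A further 6 lists passed with the preset correlation alone. Of the 11 endothelial inflammation genes that the filter left of 28, 5 rose, or 8 when adjusted over the list alone. The list had adjusted p = 1.9e-05, and adjusted p = 0.27 with an estimated correlation. Ptgs2, the inducible cyclooxygenase (chromosome 1, 150100031 to 150108227), had 19.6 ± 0.887 FPKM in RA and 36.1 ± 5.97 in HO-rWNT5A. Nfkb2 rose as well (0.30 ± 0.065), but no longer passed in 10 of 21 alternatives. Of 19 unfolded protein and integrated stress response genes 8 fell and 2 rose, or 10 and 4 when adjusted over the list alone. Herpud1 (-0.46 ± 0.058) and Asns, asparagine synthetase (-0.52 ± 0.083), were among the lower (list adjusted p = 0.000348, and adjusted p = 0.296 with an estimated correlation). Of 21 hypoxia-inducible genes 3 fell, Bnip3 (-0.57 ± 0.113), Ndrg1 (-0.41 ± 0.093) and Pfkl (-0.38 ± 0.094), and Adm rose (0.46 ± 0.102). Pfkl no longer passed in 12 of 21 alternatives. When adjusted over the list alone 6 were lower and 1 higher (list adjusted p = 0.00269, and adjusted p = 0.45 with an estimated correlation). The fibroblast markers (median -0.29, adjusted p = 0.00995), cholesterol synthesis genes (-0.08, 0.0119) and ribosomal protein genes (-0.11, 0.022) had 0 members past the threshold, or 4, 4 and 0 when adjusted over the list alone. They had adjusted p = 0.45, adjusted p = 0.619 and adjusted p = 0.857 with an estimated correlation. The filter left 5 of 10 fibroblast markers, so that list covers few members. Leaving out 1 library ended each of these 3 calls. Without HO-rWNT5A replicate 3 they had 0.103, 0.0984 and 0.23. Cholesterol synthesis genes had 0.0916 without RA replicate 1, and ribosomal protein genes 0.226 and 0.0676 without RA replicate 3 and HO-rWNT5A replicate 2. Col1a1 had 205 ± 8.51 FPKM in RA and 169 ± 25.5 in HO-rWNT5A (limma adjusted p = 0.159). The remaining 23 lists did not pass. Median, mean and test differed in sign for the NRF2, apoptosis, non-canonical WNT and mitochondrially encoded lists.

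In all, 601 genes passed in HO-rWNT5A vs RA, 335 higher and 266 lower. Slco4a1, an organic anion transporter (chromosome 2, 180456245 to 180474867), had 1.03 ± 0.0317 FPKM in RA, 1.32 ± 0.286 in HO and 3.13 ± 0.629 in HO-rWNT5A. S100a7a (1.18 ± 0.183), Lce1h (0.97 ± 0.229) and Hspa1b, an inducible heat shock protein (0.86 ± 0.118), were also among the largest rises. The largest falls included the histone genes Hist1h1b (-1.12 ± 0.122), Hist1h2bq (-0.98 ± 0.215), Hist1h3a (-0.91 ± 0.147), Hist1h2ap (-0.89 ± 0.175), Hist2h3b (-0.85 ± 0.155) and Hist1h2ag (-0.82 ± 0.125). Histone genes have near-identical copies among which fragments can be divided, so these values are uncertain. The 2 Rnu3b1 entries passed in opposite directions here. Of the genes called, 190 were also called in HO vs RA, 122 higher and 68 lower in both. Independent lists would share 4 and 2.1, and simulated groups with no effect and the same RA libraries shared 0.01 on average. Part of the excess may come from the shared RA libraries. Neither value can say how much, since groups with no effect leave almost no genes to share and independent lists have no shared libraries. The covariance of the fold changes was 0.0257, against 0.0067 from shared libraries alone. The count was 125, 170 and 192 without RA replicates 1, 2 and 3, and 204, 151 and 188 without HO-rWNT5A replicates 1, 2 and 3. The split was 209 higher and 615 lower on FPKM as deposited, 93 and 154 with libraries scaled to equal totals, and 279 and 214 with scaling to the protein-coding total. Of 26158 transcripts 10 passed, 6 higher and 4 lower.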

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

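Of these alternatives, protein-coding genes alone, the protein-coding total, the GC and length trend and the removal of HO replicates 2 and 3 together were chosen after the data were seen. Direction and side of the threshold held for the p53, mitosis and immediate early lists in all 23 alternatives of HO vs RA (adjusted p up to 0.0312, 0.0312 and 0.0395) and all 22 of HO-rWNT5A vs RA (up to 0.0382, 0.0382 and 0.0386). The estimated correlation was used on the main fit alone, and every other alternative kept the preset 0.01. Whether these lists pass with an estimated correlation and a library left out was not tested. Gene and transcript counts moved more. The cause was not tested. In the order HO vs RA, HO-rWNT5A vs HO and HO-rWNT5A vs RA, genes past the threshold were 74, 0 and 224 without a filter, and 72, 3 and 1339 with the 2 compared groups alone. Scaling to equal totals gave 44 for HO vs RA and 247 for HO-rWNT5A vs RA; protein-coding genes alone gave 439 for HO vs RA and 0 for HO-rWNT5A vs HO, the protein-coding total 0 for HO-rWNT5A vs HO, and removing the GC and length trend 469 for HO vs RA. Without HO replicates 2 and 3 the counts were 20 in HO vs RA and 0 in HO-rWNT5A vs HO, with the lone HO library assumed to vary like the others, and ribosomal protein genes turned from lower to higher in HO vs RA (adjusted p = 0.00541; 8.26e-06 to 0.327 with 1 library left out). Transcripts numbered 7, 6 and 19 without a filter, 1, 7 and 16 with the 2 groups alone, and 21 and 18 in HO vs RA and HO-rWNT5A vs HO without HO replicates 2 and 3. In HO vs RA they were 1 with a pseudocount of 0.1, 2 with 5 and 2 for protein-coding genes; in HO-rWNT5A vs RA they were 4 with a pseudocount of 0.1, 52 at a mean of at least 5 FPKM and 24 with quantile normalization. Lists past the threshold fell to 3, 0 and 4 with an estimated correlation. The replicate numbers did not pair the libraries: 3 of 9 same-numbered pairs had a correlation over 0.1 (range -0.118 to 0.279), and 0 libraries correlated best with their own number in both other groups. With the replicate block the counts were 123, 2 and 394 genes, and 1 and 3 transcripts in HO vs RA and HO-rWNT5A vs RA. Leaving out 1 library of the compared groups gave 2 to 697, 1 to 32 and 125 to 204 genes, 1 to 15, 3 to 13 and 4 to 11 transcripts, 8 to 13, 3 to 7 and 7 to 10 lists, and 0 to 12 opposite genes. Transcripts in HO vs RA numbered 2, 1 and 15 without RA replicates 1 and 2 and HO replicate 3. In HO-rWNT5A vs HO they numbered 6, 13, 6 and 8 without HO replicates 2 and 3 and HO-rWNT5A replicates 2 and 3, with 7 lists without HO replicate 3. In HO-rWNT5A vs RA they numbered 4, 4, 5 and 6 without RA replicates 2 and 3 and HO-rWNT5A replicates 1 and 2. Of 1143 values of named genes in HO vs RA under an alternative, 839 kept direction and side of the threshold, 299 no longer passed, 5 newly passed and 0 turned. With 1 library left out, 165 of these values kept them, 151 no longer passed and 1 newly passed. The values kept include those of genes that did not pass in the main fit either, such as Wnt5a and Hmox1. Depth, at 42.6 to 53.1 fragments per FPKM at 2000 bases, limits genes near the filter.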

Other observations

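The amino acid and histone groups, the values of lists over the splits, the corrections for GC content and for structural RNA, the divisions for opposite genes, both counts with a library left out and the tests of room-air levels of endothelial genes were chosen only after the results were seen. Of 29 genes of amino acid synthesis, transport and transfer RNA charging, 8 fell and 0 rose in HO vs RA (median log2 fold change -0.23), among them Aldh18a1, a proline synthesis enzyme (-0.45 ± 0.06), Lars, leucyl-tRNA synthetase (-0.40 ± 0.054), the amino acid transporter Slc7a5 (-0.39 ± 0.074) and Psat1, an enzyme of serine synthesis (-0.35 ± 0.068). In HO-rWNT5A vs RA 13 fell (median -0.27), with Slc7a5 at -0.71 ± 0.074. Without the 3 genes that had prompted the group, 26 remained, with unadjusted camera p = 7.29e-11 in HO vs RA and p = 0.0258 with an estimated correlation. In HO-rWNT5A vs RA these were 5.37e-12 and 0.0207. These p-values come from the same libraries that prompted the group, so they are not independent support for it. The named members were chosen after their values were seen.

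Of 64 replication-dependent histone genes tested, 19 fell in HO-rWNT5A vs RA (median -0.39), 2 in HO vs RA (median -0.21) and 0 in HO-rWNT5A vs HO (median -0.25). Without the genes that prompted the group, 58 remained, with unadjusted camera p = 1.53e-13, 0.000614 and 1.9e-11 in that order, and p = 0.139, 0.459 and 0.172 with an estimated correlation. These p-values too come from the libraries that prompted the group. Near-identical histone copies share fragments, so single members are uncertain.

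Endothelial genes were near 0 FPKM in libraries labelled as endothelial cells. Missing annotation is argued against, since 27 of the 27 listed genes had a transcript row, and so is a loss under hyperoxia, since 2 of 27 reached 5 FPKM in room air. A kidney lineage was weighed because genes such as Cdh6 (121 FPKM), Pax2 (37.5) and Pax8 (26.5) had been seen. Of 10 such genes seen before, 9 reached 5 FPKM. Of 15 kidney-lineage genes not looked at before, 3 did so (Npnt 11.4, Sall1 8.42 and Pkhd1 8.26), with a median of 2.96 and 4 under 1 FPKM. Of 15 lung-lineage genes not looked at before 1 did so (Etv5 15.5), with a median of 0.0727 and 13 under 1 FPKM. This list of 15 includes genes of lung epithelium such as Sftpd and Foxj1, so it cannot speak for lung endothelium. Of 5 lung-lineage genes seen before, 0 reached 5 FPKM and 5 lay under 1 FPKM. The highest were Tcf21 (0.482) and Foxf1 (0.372), the latter also on the lung capillary endothelial list. The bar set beforehand was at least 5 genes for a kidney lineage and at most 2 against it, so that lineage stays open. Pecam1 reached at most 0.143 FPKM in any of the 9 libraries, which argues against a single mislabelled library, while loss of endothelial identity in culture and another cell type in the purchased cells stay open.

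The rise of p53 targets and fall of mitosis genes in HO vs RA was set against composition of the libraries. With each library's trend with GC content and length removed, the larger adjusted p of both lists was 1.55e-16, and with structural RNA left out and libraries scaled to the protein-coding total it was 7.53e-17, which argues against either as the whole cause. The medians were 0.34 and -0.44 after the former and 0.29 and -0.46 after the latter. In the 9 other splits of the 6 libraries the smallest adjusted p was 0.000102 for p53 targets and 7.89e-05 for mitosis genes, and 7 and 9 of those splits passed. Each such split sets 2 libraries of a group against 1, so part of a difference between the groups stays in it. In the other splits of HO-rWNT5A vs HO, 0 and 2 of 9 passed. Hyperoxia, the difference that the design names, remains a candidate explanation, as does any difference in culture that went with the group.

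More genes passed in HO-rWNT5A vs RA (601) than in HO vs RA (273), a difference of 328. Of the 10 divisions of the 6 hyperoxic libraries into 3 and 3, 2 gave a difference as large, the highest other being 331, so the way these libraries happened to fall could give it. With each library left out in turn and both counts taken from the same fit, the order was kept, but the difference ran from 26 to 721. It was 30, 26 and 44 without HO-rWNT5A replicates 1, 2 and 3. With 2 HO libraries HO vs RA gave up to 697 genes, and with 2 HO-rWNT5A libraries HO-rWNT5A vs RA gave up to 204. The median SD of a gene was 0.123 in HO and 0.083 in HO-rWNT5A. A lower share of structural RNA in HO-rWNT5A is argued against by the shares themselves. They were 28.06%, 26.06% and 23.44% in HO-rWNT5A replicates 1, 2 and 3, against 27.36%, 26.51% and 20.06% in HO. The groups overlapped, and the lowest share was in HO. The ratio of the counts was 2.64 with libraries scaled to the protein-coding total. Estimated depths overlapped too, at 22600000, 21800000 and 23900000 fragments in HO-rWNT5A and 23000000, 21300000 and 21500000 in HO. An effect of WNT5A on this difference stays open.

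With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Genes past the threshold numbered 273, 1 and 601 in HO vs RA, HO-rWNT5A vs HO and HO-rWNT5A vs RA, and at most 2, 5 and 3 in another split; 1, 3 and 1 of the 10 splits gave as many. Transcripts numbered 4, 3 and 10, and at most 5, 3 and 6 in another split, with 2, 3 and 1 splits giving as many. Lists past the threshold numbered 10, 4 and 10, and at most 10, 7 and 10 in another split, with 2, 9 and 2 splits giving as many. The 0 genes opposite in HO vs RA and HO-rWNT5A vs HO were matched or exceeded in 100 of 100 divisions of the 9 libraries drawn, as a count of 0 must be, so this decides nothing. The highest other count was 190. That division and 1 with 135 had the 3 RA libraries as the shared group, so they hold the difference from RA, and the 97 others gave at most 2.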
